A study of Mus musculus with 16 samples.

How the data were processed

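Pancreata of mouse embryos at embryonic day 15.5 were profiled by RNA sequencing in 4 genotypes. The labels give 4 control, 4 Pdx1 heterozygous, 3 Oc1 heterozygous and 5 double heterozygous libraries, 16 in all. The Pdx1 heterozygotes carry a lacZ allele at Pdx1, and Oc1 is the protein whose gene is listed as Onecut1. Per the labels' protocols, pancreata were dissected into Trizol and libraries were prepared from total RNA with a TruSeq kit. The labels do not say whether the libraries of a group come from separate litters, so the p-values measure the spread between these libraries. The strain is a mixed background per the labels.

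Per the submitters' processing notes, CASAVA 1.8.2, edgeR and genome build mm9 were used, and no version of edgeR or aligner is given in the sources used here. The reference annotation at hand is of another build, so no coordinates are printed. The table of read counts holds 16 columns named by flow cell, lane and index, which no label ties to a sample, so these 16 per-library columns were not used in any step. Only its gene symbols were read, 22869 different ones, as the list of genes counted. Library depth per sample was therefore not analysed here, and neither were values per library, means with SD, outlying libraries or any refit.

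All values come from the authors' comparison table, which holds 2283 genes in 5 blocks of 4 values. Per the file headers, each block gives a log2 fold change, a mean log2 CPM, a p-value and an adjusted p (false discovery rate) computed by the authors. The logarithm was taken as base 2, since a natural logarithm would put the gene with the highest mean, 13.97, above the possible maximum of CPM. The smallest p-value of each block multiplied by 22869 differed from the deposited adjusted p by at most 0.478%, as Benjamini-Hochberg adjustment over 22869 genes gives. Each gene of the table had an adjusted p under 0.1 together with a fold change of at least 1.5 in at least 1 block. The largest of the smallest adjusted p-values per gene was 0.0999. For each gene the largest fold change with adjusted p under 0.1 was taken, and the smallest of these was 1.5007. The table was therefore taken to list each block's genes completely only above this fold. The ranks implied by the adjusted p show that more genes passed the p-value threshold than are listed. A gene was counted as changed where the adjusted p was under 0.05 and the fold change at least 1.5, and the number past the adjusted p alone, from the ranks, is given beside it as a lower bound. The adjusted p was chosen before the data were examined, and the fold minimum was added after this listing rule was found. An unlisted gene was taken not to have reached adjusted p 0.1 and 1.5-fold together in any of the 5 blocks.

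In 12 rows an empty block is marked by a run of dashes; in 8 of them the later values stand 1 column to the right and were moved back. In 3 rows the symbol is a number, and these rows were counted but not named. The headings of blocks 4 and 5 did not match their fold changes. Block 4, headed double against Pdx1 heterozygote, equalled Pdx1 minus double heterozygote in 2275 of 2275 rows with values (tolerance 1e-06), so its sign was turned. Block 5, headed double against Oc1 heterozygote, equalled Pdx1 minus Oc1 heterozygote in 2279 of 2279 rows and was used as that comparison. The same arithmetic would hold with the headings of blocks 1 and 3 exchanged. This was checked on the variance of each fold change, taken as the square of the fold change divided by the normal quantile of its p-value. For genes with a mean log2 CPM above 4, the median variance relative to block 1 was 1.15, 0.905, 0.897 and 1.14 in blocks 2 to 5. The group sizes give 1.17, 0.9, 0.9 and 1.17 with the headings of blocks 1 to 3 as printed, and 1.30, 1.11, 1 and 1.19 with blocks 1 and 3 exchanged. The headings of blocks 1 to 3 were kept.

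The edgeR quasi-likelihood fits chosen before the data were examined need counts per sample and were not run; the adjusted p-values of 5 comparisons are those of the authors. The other 2 comparisons of the design, double against Oc1 heterozygote and the interaction (double minus Oc1 heterozygote, less Pdx1 heterozygote minus control), were derived from the table. Their fold changes are sums of the authors' log2 fold changes. The variance of the interaction was the mean of that from blocks 3 and 5 and that from blocks 2 and 4, each a sum over independent groups; the 2 estimates had a median ratio of 1.00 (5th to 95th percentile 0.980 to 1.03, 1956 genes). Blocks with a p-value of 0.9 or more gave no variance, which left 2265 genes with an interaction test and 18 without. The variance of double against Oc1 heterozygote was the interaction variance scaled by the group sizes. Two-sided normal p-values were adjusted by Benjamini-Hochberg over 22869 genes with unlisted genes set to 1, so unlisted genes are never counted. The derivation was tested on simulated counts of 22869 genes, with the same assumed depth in each library and the listing rule of the table. For the interaction it recovered 29% of genes with a departure of 1 on the log2 scale and 72% of those with a departure of 2, and 3.81% of its calls were false. For double against Oc1 heterozygote 3.94% of calls were false. The simulated tests were given the true spread of each gene, and the Pdx1 group had no effect. Error rates in the real data may therefore be higher.

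A total of 24 gene lists was written before the data were examined: endocrine progenitor, beta cell, alpha cell, delta, PP and epsilon cell, pan-endocrine secretory, acinar enzymes, acinar transcription factors, pancreatic progenitor and trunk, ductal, Notch pathway, cell cycle and ER stress; the other cell types mesenchyme, mesothelium, endothelium, neural and Schwann, erythroid, leukocyte, spleen anlage, stomach and intestine, and liver; and immediate early, hypoxia and glycolysis, and sex genes. The camera tests planned for them need counts per sample. Instead, the changed members of a list in each direction were set against the 22869 genes by a one-sided Fisher's exact test, adjusted by Benjamini-Hochberg over 46 tests per comparison (sex genes left out). This test treats genes as independent, which co-expressed genes are not. Counts adjusted over the list alone treat unlisted members as p-value 1 and keep the fold minimum.

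Named genes follow a rule written before the data were examined: Pdx1 and Onecut1 in each comparison; the 10 highest and 10 lowest fold changes with adjusted p under 0.05 and mean log2 CPM of at least 1, without provisional symbols and sex genes; up to 6 members of each list with the smallest p-values past the threshold; and, for a list of the planned biology with none, the 3 listed members with the highest mean. Genes named outside it are said to be. The reads of near-identical copies, such as the trypsin genes (Prss1, Prss2, Prss3, Try5), Ins1 and Ins2, or Lgals4 and Lgals6, and of genes with an antisense partner, such as Xist and Tsix, may not be separable. Fold changes against control were compared between genotypes beside 100 simulated draws of unchanged groups that share the controls. Alternatives to the threshold, fold minimum, expression minimum, block headings, standard errors, adjustment and background were tried. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.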

Results

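RNA of whole pancreata from mouse embryos at embryonic day 15.5 was sequenced from 4 control, 4 Pdx1 heterozygous, 3 Oc1 heterozygous and 5 double heterozygous libraries. Pdx1 is a homeodomain factor needed for pancreas formation and for beta cells. Oc1, encoded by Onecut1, is a factor of pancreatic progenitors and ducts that acts upstream of Neurog3. The comparisons ask whether losing 1 copy of each gene together changes the endocrine program more than losing either alone. The values analysed were the log2 fold changes and adjusted p-values of the authors' comparison table, which lists 2283 of 22869 genes. Values and depths per library were not analysed here.

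Against control, the first question was whether the targeted genes were lower in the genotypes that carry the alleles. In the authors' deposited table Pdx1 fell in the Pdx1 heterozygotes (log2 fold change -0.47, 1.39-fold, adjusted p = 0.00427) and in the double heterozygotes (-0.61, 1.52-fold, adjusted p = 5.03e-07). It stood at -0.12 in the Oc1 heterozygotes in the authors' deposited table (adjusted p = 0.586). The same comparisons in the authors' deposited table gave Onecut1 at -0.48 in the Oc1 heterozygotes (adjusted p = 0.146), -0.27 in the double heterozygotes (adjusted p = 0.954) and 0.42 in the Pdx1 heterozygotes (adjusted p = 0.828). None of these passed the threshold. Between genotypes, Onecut1 was lower in the double than in the Pdx1 heterozygotes by the authors' deposited table (-0.70, adjusted p = 0.0319) and higher in the Pdx1 than in the Oc1 heterozygotes (0.90, adjusted p = 0.00191). Onecut1 transcript in the carriers of the Oc1 allele was thus not separated from control. Reads of a mutant transcript, if one is made, may be counted with the normal ones. The labels do not say whether the counted exons lie in the deleted part.

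Double heterozygous pancreata had lower insulin and beta cell genes than control pancreata. Ins1 and Ins2, the insulin genes, fell by 2.36 and 2.18 on the log2 scale in the authors' deposited table (5.12-fold and 4.53-fold lower; adjusted p = 8.89e-23 and 7.89e-25). Iapp, the islet amyloid peptide secreted with insulin, fell by 1.92 (adjusted p = 1.79e-18 in the authors' deposited table). G6pc2, an islet glucose-6-phosphatase, fell by 1.69, Mafa, an activator of insulin transcription, by 1.57, and Kcnj11, a subunit of the beta cell potassium channel, by 0.83 (adjusted p = 3.59e-11, 2.76e-05 and 3.46e-12 in the authors' deposited table). Of 31 beta cell genes, 17 fell and none rose (0.172 by chance; Fisher's exact test, adjusted p = 1.71e-29). Adjusted over the list alone 17 fell, and 14 did not pass. Pdx1 itself, whose gene carries the mutated allele, is among the 17.

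Other endocrine lists fell as well in the double heterozygotes. Of 35 endocrine progenitor genes, 7 fell (Fisher's exact test, adjusted p = 9.37e-09; 9 adjusted over the list alone). They include Neurog3, which commits progenitors to the endocrine lineage (-0.75, adjusted p = 0.00025 in the authors' deposited table), its target Pax4 (-0.72, adjusted p = 0.0259) and Pax6 (-0.64, adjusted p = 7.31e-06). Neurod1 stood at -0.41 with adjusted p = 0.0338 in the authors' deposited table, under the fold minimum. Of 45 pan-endocrine secretory genes, 10 fell and 1 rose (Fisher's exact test for the lower genes, adjusted p = 1.21e-12; 11 lower adjusted over the list alone). The prohormone convertase Pcsk2 stood at -0.89 (adjusted p = 2e-06), secretagogin (Scgn) at -0.69 (adjusted p = 0.000202) and, higher, Rab27b at 0.74 (adjusted p = 0.0247) in the authors' deposited table. Of 14 alpha cell genes, 3 fell (Fisher's exact test, adjusted p = 0.000446; 4 adjusted over the list alone). Glucagon (Gcg) fell by 0.76 (adjusted p = 0.007 in the authors' deposited table), and Pcsk2 belongs to this list too. Of 14 delta, PP and epsilon cell genes, 3 fell (Fisher's exact test, adjusted p = 0.000446; 4 adjusted over the list alone). Somatostatin (Sst) fell by 0.95, gastrin (Gast) by 1.55 and Rbp4 by 0.78 (adjusted p = 0.0126, 5.91e-07 and 1.09e-09 in the authors' deposited table). Mnx1, a factor of early pancreas and beta cells, fell by 1.44 and Nkx6-2 rose by 0.73 (adjusted p = 1.61e-07 and 0.0138 in the authors' deposited table). The pancreatic progenitor and trunk list did not pass (2 lower, 1 higher of 31; adjusted p = 0.0736 and 0.237 by Fisher's exact test).

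Few exocrine genes passed the threshold in the double heterozygotes, though the 44 listed acinar enzymes had a median log2 fold change of 0.55 against control. Of 50 acinar enzyme genes 1 rose and none fell (Fisher's exact test, adjusted p = 0.318 and 1), while 5 were higher and 1 lower adjusted over the list alone. At an unadjusted p under 0.05 the authors' edgeR test had 13 higher and 4 lower. The one that rose was Reg1, a secreted acinar protein (1.75, adjusted p = 3.59e-07 in the authors' deposited table). No member of the acinar transcription factor, ER stress or Notch pathway lists passed in the authors' edgeR test (2, 1 and 0 listed members higher and 0 lower at an unadjusted p under 0.05). Xbp1 stood at 0.27, Calr at 0.02 and Lfng at 0.07 in the authors' deposited table. The cell cycle and endothelium lists had no listed member in any comparison. Among other cell types, 6 of 19 liver genes fell (Fisher's exact test, adjusted p = 9.37e-09; 7 adjusted over the list alone). Alb stood at -2.25, Apoh at -2.28 and Fgb at -1.28 (adjusted p = 0.00839, 0.0254 and 0.0141 in the authors' deposited table). In the same list 1 gene rose, Vtn at 0.62 (adjusted p = 2.18e-05 in the authors' deposited table). Of the stomach and intestine genes, Cldn18 rose (1.67) and Apoa1 and Gkn2 fell (-1.52 and -5.91 in the authors' deposited table); the list did not pass (adjusted p = 0.0645 for the lower genes, Fisher's exact test).

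In all, 170 genes changed in the double heterozygotes, 43 higher and 127 lower. At least 244 passed the adjusted p of the authors' deposited table without the fold minimum. Among genes with a mean log2 CPM of at least 1, the most raised was Kap, a kidney androgen-regulated gene (10.59, adjusted p = 0.00418 in the authors' deposited table), followed by Angptl1 (2.22), Sostdc1 (3.48-fold higher), Reg1 and Cym (1.72). The lowest outside the beta cell and liver lists were Nepn (-1.93) and Arhgap36 (-1.60; adjusted p = 2.75e-09 and 2.14e-08 in the authors' deposited table). With 6 gene lists past Fisher's exact test, the double heterozygotes had 5 endocrine lists and the liver list lower. The delta, PP and epsilon cell list did not pass with the listed genes as background (adjusted p = 0.0708). The liver decrease was not particular to this genotype. In the Pdx1 heterozygotes 7 liver genes were also lower adjusted over the list alone, though none was called over all genes. Both comparisons use the same control libraries, so these decreases are not independent. Whether liver tissue was carried along in some dissections was not tested.

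**Figure D1:**
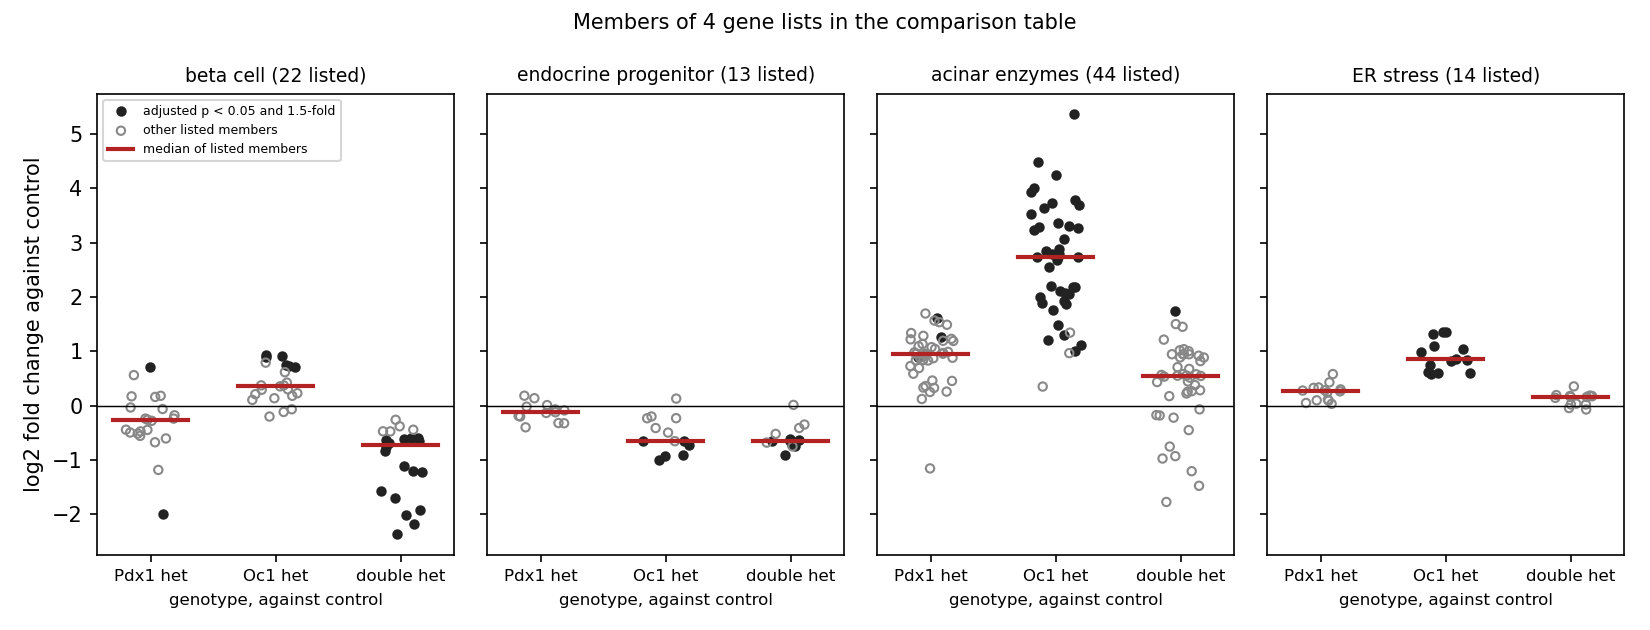
Log2 fold change against control (vertical axis) of the listed members of the beta cell, endocrine progenitor, acinar enzyme and ER stress lists in Pdx1, Oc1 and double heterozygotes (horizontal axis). Each point is 1 gene from the authors' deposited table, filled where adjusted p was under 0.05 and the fold at least 1.5, and the red line is the median of listed members: -0.27, 0.36 and -0.73 for beta cell genes, -0.12, -0.64 and -0.64 for endocrine progenitor genes, 0.95, 2.73 and 0.55 for acinar enzymes and 0.27, 0.85 and 0.16 for ER stress genes.

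Pdx1 heterozygous pancreata differed from control in few genes, and the change in insulin transcripts did not pass. Ins1 and Ins2 stood at -0.50 and -0.52 in the authors' deposited table (adjusted p = 0.763 and 0.527). Of the beta cell genes, Npy was lower (3.99-fold, adjusted p = 0.000278), and so were Kcnj11 (-0.56, adjusted p = 0.000533) and Pdx1 in the authors' deposited table. The glucose transporter Slc2a2 rose by 0.70 (adjusted p = 0.0321 in the authors' deposited table). At an unadjusted p under 0.05 the authors' edgeR test had 10 listed beta cell genes lower and 2 higher. With the fold minimum 1 beta cell gene fell and 1 rose, and the list did not pass (Fisher's exact test, adjusted p = 0.207 and 0.406; 3 lower and 1 higher adjusted over the list alone). No endocrine progenitor gene passed in the authors' edgeR test (1 listed member lower at an unadjusted p under 0.05). Neurog3 stood at -0.32 and Sox4 at -0.14 in the authors' deposited table. Ghrelin (Ghrl) and Rab27b rose by 0.68 and 0.81 (adjusted p = 0.0226 and 0.0366 in the authors' deposited table). Acinar enzymes were the 1 list to pass, with 3 of 50 higher (Fisher's exact test, adjusted p = 0.00685; 16 higher and 1 lower adjusted over the list alone). At an unadjusted p under 0.05 the authors' edgeR test had 21 higher and 1 lower. The list did not pass with the listed genes as background (adjusted p = 0.845). The genes were Reg1 at 1.62, Sycn, a zymogen granule protein, at 1.27 and Erp27 at 0.90 (adjusted p = 9.56e-05, 0.0446 and 0.0446 in the authors' deposited table).

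A total of 57 genes changed in the Pdx1 heterozygotes, 47 higher and 10 lower, and at least 72 passed the adjusted p alone. At the top, among genes with a mean log2 CPM of at least 1, were Kap (11.01, adjusted p = 0.0101), Lgals6 and Lgals4, galectins of gut epithelium (3.69 and 3.52, adjusted p = 0.00964 and 0.00936), Agr2 (2.31) and Angptl1 (1.83) in the authors' deposited table. The lowest in the authors' deposited table were Npy, the opioid receptor Oprd1 (-1.37), Nepn (-1.31) and Tmem171 (-1.05). Lgals4 belongs to the stomach and intestine list, of which it was the 1 member to change (Fisher's exact test for the higher genes, adjusted p = 0.406). Adjusted over the list alone, 6 of its members were higher and 2 lower. Of 19 liver genes none was lower (7 adjusted over the list alone, and 7 at an unadjusted p under 0.05 in the authors' edgeR test) and 1 was higher (adjusted p = 0.353, Fisher's exact test).

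Oc1 heterozygous pancreata had far higher acinar enzyme transcripts than control pancreata. Of 50 acinar enzyme genes 41 rose and none fell (1.83 by chance; Fisher's exact test, adjusted p = 3.7e-49; 42 adjusted over the list alone). The median log2 fold change of the 41 was 2.73 and the highest 5.36. Dmbt1 rose by 5.36, carboxypeptidase B1 (Cpb1) by 4.49, Zg16 by 4.24, the trypsin gene Try4 by 3.93 and the elastase Cela2a by 3.79 in the authors' deposited table (adjusted p = 1.54e-17, 6.06e-10, 3.24e-06, 5.09e-06 and 2.42e-08). Of 11 acinar transcription factors 6 rose (Fisher's exact test, adjusted p = 1.06e-05; 6 adjusted over the list alone). Rbpjl stood at 1.53, Bhlha15 at 0.92, Ptf1a at 0.84 and Xbp1 at 0.78 (adjusted p = 2.33e-07, 2.25e-05, 0.000203 and 3.69e-07 in the authors' deposited table). Of 21 ER stress genes, many of them chaperones and degradation factors of secretory cells, 14 rose (Fisher's exact test, adjusted p = 1.42e-14; 14 adjusted over the list alone). Sdf2l1 stood at 1.36, Herpud1 at 1.35 and Sel1l at 1.31 (adjusted p = 3.2e-11, 1.25e-11 and 3.09e-10 in the authors' deposited table).

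In the Oc1 heterozygotes endocrine progenitor genes were lower, while beta cell and delta, PP and epsilon cell genes were higher. Of 35 endocrine progenitor genes 6 fell (Fisher's exact test, adjusted p = 0.00229; 6 adjusted over the list alone). Pax4 stood at -0.93, Sox4 at -0.91 and Neurog3 at -0.65 (adjusted p = 0.000787, 1.1e-08 and 0.00269 in the authors' deposited table). Of 31 beta cell genes 6 rose (Fisher's exact test, adjusted p = 0.00515; 6 adjusted over the list alone). Ins1 rose by 0.93, Ins2 by 0.90 and Iapp by 0.72 (adjusted p = 0.00192, 0.000556 and 0.0108 in the authors' deposited table). Of 14 delta, PP and epsilon cell genes 4 rose and 1 fell (Fisher's exact test for the higher genes, adjusted p = 0.00758; 4 adjusted over the list alone). Sst rose by 1.01 and Ppy by 0.97 (adjusted p = 0.00245 and 0.000367 in the authors' deposited table). Among pan-endocrine secretory genes 2 rose and 2 fell, Rab27b and Scg2 at 1.17 and 0.71 and Scg5 and Chgb at -1.18 and -0.82 in the authors' deposited table. That list did not pass (adjusted p = 0.92 and 0.747, Fisher's exact test), nor did the alpha cell list (1 of 14 higher, adjusted p = 0.849). With the 2283 listed genes as the background, the acinar enzymes and ER stress lists passed, and the endocrine lists and acinar transcription factors did not.

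Neural and spleen anlage genes were lower in the same libraries. Of 22 neural and Schwann genes 7 fell and 1 rose (Fisher's exact test for the lower genes, adjusted p = 1.06e-05; 10 lower adjusted over the list alone; adjusted p = 0.318 with the listed genes as background). Nefl stood at -1.50, Fabp7 at -1.22 and Stmn2 at -0.99, and Ret at 0.96 (adjusted p = 0.00293, 6.6e-05, 9.73e-05 and 1.93e-05 in the authors' deposited table). All 3 listed genes of the spleen anlage fell (3 of 6; Fisher's exact test, adjusted p = 0.00248; 3 adjusted over the list alone), too few members for the test with the listed genes as background. Of the mesenchyme list Nkx3-2, which also belongs to the spleen anlage list, Tcf21 and Pdgfra fell (-1.67, -1.11 and -0.61 in the authors' deposited table). That list did not pass (3 of 37, adjusted p = 0.244 by Fisher's exact test). Of the erythroid genes 3 of 19 fell, led by embryonic globin Hbb-y (-2.26, adjusted p = 0.000495 in the authors' deposited table), and the list did not pass (Fisher's exact test, adjusted p = 0.0625). The complement gene C1qa rose by 1.85, and the hypoxia-related genes Egln3, Car9 and Ndrg1 by 1.55, 1.12 and 0.99 (adjusted p = 1.43e-14, 6.28e-07, 5.79e-08 and 6.62e-06 in the authors' deposited table). The hypoxia and glycolysis list did not pass (3 of 18; Fisher's exact test, adjusted p = 0.121). Neither the ductal (4 higher, 2 lower of 39; adjusted p = 0.203 and 0.723) nor the Notch pathway list (1 and 1 of 28; adjusted p = 1 and 0.92) passed Fisher's exact test. Nor did the immediate early (2 of 20 lower, adjusted p = 0.286), mesothelium (1 of 10 lower, adjusted p = 0.662) and leukocyte lists (1 of 28 higher, adjusted p = 1).

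With 1428 genes changed, 836 higher and 592 lower, the Oc1 heterozygotes stood farther from control in number of genes than the other genotypes. At least 3462 genes (15.1% of those counted) passed the adjusted p alone. These 3 libraries also differed in sex-linked genes: the X-inactivation transcript Xist stood at -8.78, its antisense Tsix at -7.51 and the Y-linked Ddx3y at 2.64 against control (adjusted p = 0.00249, 4.98e-08 and 0.037 in the authors' deposited table). In the Pdx1 and double heterozygotes Xist stood at -0.45 and -0.59 in the authors' deposited table (adjusted p = 1 for both).

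**Figure D2:**
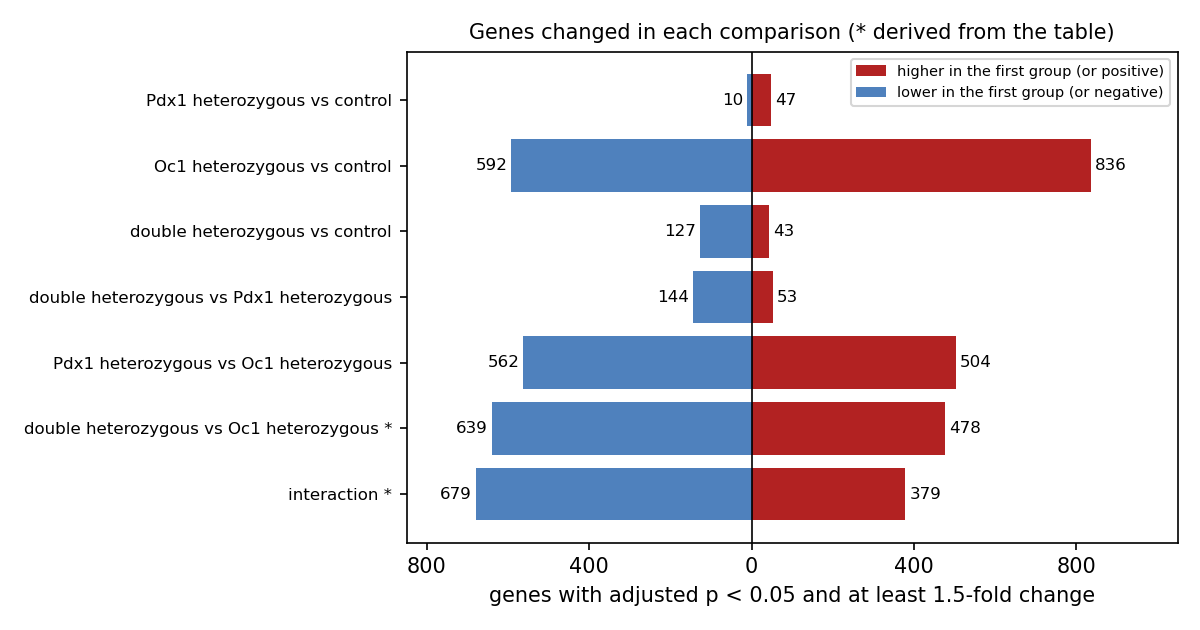
Number of genes (horizontal axis) with adjusted p under 0.05 and at least 1.5-fold change in each comparison (vertical axis), higher in the first group to the right and lower to the left; a star marks comparisons derived from the table. The Pdx1 heterozygotes differed from control in 57 genes, the double heterozygotes in 170 and the Oc1 heterozygotes in 1428.

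The comparison of double with Pdx1 heterozygotes asks what the loss of 1 Oc1 copy adds when Pdx1 is already reduced. Insulin genes were lower in the double heterozygotes: Ins1 by 1.86 and Ins2 by 1.66 (3.63-fold and 3.17-fold), Iapp by 1.31 and G6pc2 by 1.43 in the authors' deposited table with its sign turned (adjusted p = 1.18e-13, 1.08e-13, 9.94e-08 and 2.23e-07). Of 31 beta cell genes 7 fell (Fisher's exact test, adjusted p = 1.81e-08; 11 adjusted over the list alone). Of 45 pan-endocrine secretory genes 11 fell (adjusted p = 1.63e-13 by Fisher's exact test; 12 adjusted over the list alone). Scg5 stood at -1.22, Pcsk2 at -0.84 and Syt13 at -0.60 in the authors' deposited table. Among 14 delta, PP and epsilon cell genes 3 fell (Fisher's exact test, adjusted p = 0.000973; 3 adjusted over the list alone). These were Sst at -1.09, Gast at -0.96 and Ghrl at -0.70 in the authors' deposited table. In the endocrine progenitor list 3 of 35 fell (Fisher's exact test, adjusted p = 0.00794; 3 adjusted over the list alone). Pax4 stood at -0.73, Neurod1 at -0.59 and Neurog3, not past the threshold, at -0.43 (adjusted p = 0.169 in the authors' deposited table). Pdx1 did not differ detectably (-0.13, adjusted p = 0.929 in the authors' deposited table).

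Genes of other tissues also differed between double and Pdx1 heterozygotes. The galectins Lgals6 and Lgals4 were lower by 3.61 and 3.32, and the intestinal genes Cdx1 and Cdh17 by 3.90 and 2.49 in the authors' deposited table (adjusted p = 0.000929, 0.0014, 0.00476 and 0.00719). Lgals4, Cdx1 and Cdh17 are the 3 of 27 stomach and intestine genes that fell (Fisher's exact test, adjusted p = 0.00491; 5 adjusted over the list alone). Smooth muscle genes Cnn1 and Myh11 were at -2.82 and -1.91, while the mesenchymal factors Nkx3-2 and Barx1 rose by 1.07 and 0.96 in the authors' deposited table. Against control, Lgals4 was raised in the Pdx1 heterozygotes (3.52) and was not among the genes changed in the double heterozygotes. Cnn1 and Myh11 also stood above control in the Pdx1 heterozygotes, not past the threshold. The decrease of these genes can thus not be credited to the loss of the Oc1 copy alone. Of 37 mesenchyme genes 2 rose and 1 fell (adjusted p = 0.0153 and 0.6, Fisher's exact test). Lists of the spleen anlage (2 of 6 higher, adjusted p = 0.000973), ductal genes (3 of 39 lower, adjusted p = 0.00967), pancreatic progenitor and trunk (3 lower and 1 higher of 31, adjusted p = 0.00635 and 0.266) and acinar enzymes (4 of 50 lower, adjusted p = 0.00255) passed Fisher's exact test. The acinar genes were Prss1, Prss2, Prss3 and Gp2. Of these 10 passing lists 9 were also tested with the listed genes as background, where the beta cell and pan-endocrine lists passed; the spleen anlage list has too few listed members. In all 197 genes changed, 53 higher and 144 lower, and at least 309 passed the adjusted p alone. The heading of this block taken as printed would turn every direction.

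The single heterozygotes were also compared with each other in the authors' table, where 1066 genes changed, 504 higher and 562 lower in the Pdx1 than in the Oc1 heterozygotes. At least 2557 passed the adjusted p alone. Acinar enzymes were lower in the Pdx1 heterozygotes (36 of 50; Fisher's exact test, adjusted p = 1.1e-45; 38 adjusted over the list alone), as were beta cell genes (11 lower, 1 higher of 31; adjusted p = 2.19e-09 and 0.887; 0.0794 for the lower genes with the listed genes as background). Cpb1 stood at -3.21, Ins2 at -1.42 and Ins1 at -1.42 in the authors' deposited table. Mesenchymal genes were higher (7 of 37; Fisher's exact test, adjusted p = 0.000106), led by Myh11 at 3.22, and so were stomach and intestine genes (6 of 27, adjusted p = 0.000144; 0.417 with the listed genes as background), led by Lgals4 at 3.45 in the authors' deposited table. Higher too were the neural and Schwann (6 of 22), pancreatic progenitor and trunk (4 of 31), endocrine progenitor (4 of 35) and ductal lists (4 of 39; adjusted p = 6.99e-05, 0.0232, 0.0325 and 0.0397, Fisher's exact test). The acinar transcription factors (5 of 11), ER stress (6 of 21), delta, PP and epsilon cell (3 of 14) and hypoxia and glycolysis lists (3 of 18) were lower (adjusted p = 5.47e-05, 7.74e-05, 0.0232 and 0.0381, Fisher's exact test). With the listed genes as background the acinar enzymes and mesenchyme lists passed (adjusted p = 3.14e-14 and 0.022), and the hypoxia and glycolysis list has too few listed members. Xist was higher by 8.32 (adjusted p = 0.00543 in the authors' deposited table).

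Double and Oc1 heterozygotes were compared through fold changes derived from the authors' table, to ask what the loss of 1 Pdx1 copy adds when Oc1 is reduced. The Oc1 heterozygotes also differed from the other groups in sex-linked genes, and sex was not adjusted for. A difference in this comparison can therefore not be credited to the Pdx1 copy alone. Ins2 was lower by 3.08 ± 0.21 (SE) on the log2 scale and Ins1 by 3.28 ± 0.23 in the double heterozygotes, with Iapp at -2.64 ± 0.21 (adjusted p = 2.32e-45, 1.25e-40 and 9.8e-32, normal test on the derived standard error). Of 31 beta cell genes 18 fell (Fisher's exact test, adjusted p = 2.8e-19), of 14 alpha cell genes 6 (adjusted p = 1.31e-05), of 45 pan-endocrine secretory genes 8 and of 14 delta, PP and epsilon cell genes 5 (adjusted p = 0.000233 for both). Acinar enzymes were lower in 39 of 50 (adjusted p = 9.72e-50), ER stress genes in 9 of 21 (adjusted p = 3.23e-08) and acinar transcription factors in 3 of 11 (adjusted p = 0.0154), by Fisher's exact test. The mesenchyme (6 of 37), spleen anlage (3 of 6) and neural and Schwann lists (3 of 22) were higher (Fisher's exact test, adjusted p = 0.000696, 0.000983 and 0.0473). With the listed genes as background the pan-endocrine, delta, PP and epsilon cell, acinar transcription factor and neural lists did not pass (adjusted p = 0.236, 0.469, 0.957 and 1), and the spleen anlage list was not tested. Pdx1 was lower by 0.49 ± 0.11 (SE; adjusted p = 0.000118) and Neurog3 stood at -0.10 ± 0.17 (adjusted p = 1). By this test 1117 genes changed, 478 higher and 639 lower, and Xist was higher by 8.18 ± 1.92 (adjusted p = 0.000619).

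The interaction asks whether the Pdx1 allele changed a gene by a different amount on the Oc1 heterozygous than on the Oc1 wild-type background. It uses the Oc1 heterozygotes, whose sex-linked genes differed from those of the other groups. A departure can therefore not be credited to the alleles alone. Insulin genes departed downward from the sum of the single effects: Ins1 by -2.79 ± 0.33 (SE) and Ins2 by -2.57 ± 0.29 on the log2 scale (adjusted p = 6.63e-14 and 8.29e-15, normal test on the derived standard error). Iapp stood at -2.03 ± 0.29, G6pc2 at -2.17 ± 0.32 and Sst at -2.10 ± 0.36 (adjusted p = 4.32e-09, 6.25e-09 and 1.01e-06). Negative interactions were found for 15 of 31 beta cell genes (Fisher's exact test, adjusted p = 4.59e-14; 17 adjusted over the list alone), 4 of 14 alpha cell genes (adjusted p = 0.00348), 3 of 14 delta, PP and epsilon cell genes (adjusted p = 0.0309) and 7 of 45 pan-endocrine secretory genes (adjusted p = 0.00255). With the listed genes as background the beta cell, acinar enzymes and ER stress lists passed (adjusted p = 0.00192, 3.85e-16 and 0.000302), and the alpha cell, delta, PP and epsilon cell and pan-endocrine lists did not (adjusted p = 0.571, 1 and 0.589). In contrast, Neurog3 (0.22 ± 0.23), Pax4 (0.20 ± 0.30) and Myt1 (0.03 ± 0.22) did not depart detectably from additivity (adjusted p = 1 for each), and of the endocrine progenitor list 1 gene, Sox4, had a positive interaction (1.06 ± 0.18, adjusted p = 1.37e-06).

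Most acinar enzyme genes had negative interactions. Of 50 acinar enzymes 40 were negative (Fisher's exact test, adjusted p = 8.69e-51; 43 adjusted over the list alone). Dmbt1 stood at -5.89 ± 0.73 (SE), Try5 at -5.73 ± 0.80 and Cpb1 at -4.76 ± 0.81 (adjusted p = 1.83e-12, 9.33e-10 and 7.75e-07). Of 21 ER stress genes 12 were negative (adjusted p = 1.48e-12), of 11 acinar transcription factors 4 (adjusted p = 0.00197) and of 39 ductal genes 5 (adjusted p = 0.026). Positive interactions were found for 4 of 37 mesenchyme, 4 of 22 neural and 3 of 6 spleen anlage genes (adjusted p = 0.0161, 0.00279 and 0.000993, all by Fisher's exact test). With the listed genes as background the acinar transcription factor, ductal, mesenchyme and neural lists did not pass (adjusted p = 0.571, 0.581, 0.477 and 0.593), and the spleen anlage list was not tested. A total of 1058 genes passed, 379 positive and 679 negative. Of these, 947 also differed between Oc1 heterozygotes and control and 49 between double heterozygotes and control, so most interactions were in genes that changed in the Oc1 heterozygotes. Part of this overlap is built in. The interaction contains the Oc1 difference from control with its sign turned, and 1428 of the 2283 listed genes changed in that comparison. Xist passed as well (8.64 ± 2.67, adjusted p = 0.0282).

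Fold changes against control were compared between genotypes across 1605 listed genes with a mean log2 CPM of at least 1; genes are not independent replicates, and the comparisons share the control libraries. Pearson's r across genes was 0.64 between Pdx1 and double heterozygotes, 0.32 between Oc1 and double and 0.45 between Pdx1 and Oc1, where 100 simulations of unchanged groups gave means of 0.53, 0.49 and 0.47. The covariances were 0.173, 0.172 and 0.236 against simulated 0.0305, 0.0306 and 0.0310. Without the minimum of log2 CPM, r was 0.54, 0.45 and 0.38 in the same order, against simulated 0.53, 0.49 and 0.46. The excess of the first pair over simulation was then lost. Of the genes changed in the double heterozygotes, 16 of 43 higher and 7 of 127 lower changed the same way in the Pdx1 heterozygotes, where independent lists would share 0.0884 and 0.0555. With the Oc1 heterozygotes 27 higher and 22 lower genes were shared (1.57 and 3.29 for independent lists) and 11 went in opposite directions. Pdx1 and Oc1 heterozygotes shared 20 higher and 5 lower genes (1.72 and 0.259 for independent lists), with 2 opposite. Simulated unchanged groups shared 0 in each pair. Unchanged groups are bound to give almost no calls, so this does not measure what the shared controls add to the counts. The shared controls could not be split without values per library, and the listed genes are selected for change in at least 1 comparison.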

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

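The tests of a larger acinar share, of sex, of a common endocrine decrease and of the epithelial share were chosen after the results were seen; the test on oncofetal genes was set before its genes were looked up, with the fold minimum added to it afterwards. Fold changes departed from the sum of the single heterozygous effects in 1058 genes by the interaction test, including 15 beta cell, 40 acinar enzyme and 12 ER stress genes, all of the latter 3 sets negative. Libraries that stand apart from their group could not be looked for, since no value per library was used, and for the same reason other splits of the samples were not counted.

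The higher acinar and ER genes of the Oc1 heterozygotes were weighed first. A larger share of acinar cells as the whole cause would lower the markers of other cell types together. Instead 6 beta cell genes were higher against control. As it predicts, 7 neural, 6 endocrine progenitor, 3 mesenchyme, 3 spleen anlage and 3 erythroid genes were lower. Nkx3-2 is in both the mesenchyme and spleen anlage counts, and the mesenchyme and erythroid lists did not pass. Other lists did not go that way: 4 ductal genes were higher and 2 lower, 1 leukocyte gene was higher and 0 lower, and no endothelium gene was called. A larger acinar share as part of the cause stays open. A more advanced stage of development is a candidate explanation that the test cannot single out. Of 16 oncofetal genes, which decline as organs mature, 4 were lower in the Oc1 heterozygotes and 0 higher. These were Lin28b, Hmga2, Igf2bp1 and Trim71 (adjusted p = 0.00182, 5.34e-08, 1.14e-05 and 0.00357 in the authors' deposited table). By chance over all 22869 genes 0.414 would be lower (exact p = 0.000631, Fisher's exact test, one-sided). The other 12 are unlisted, and 592 of the 2283 listed genes were lower. All 4 also stood below the same controls in the Pdx1 and double heterozygotes, none past the threshold. A different mix of cells in whole pancreata could lower them too, which the test does not separate from stage. A sex difference of the embryos stays open, because Xist stood at -8.78 in the authors' deposited table. No value per library ties acinar genes to sex within a group. The double heterozygotes carry the Oc1 allele too, yet 1 of 50 acinar enzymes and 0 of 21 ER stress genes were higher against control. Medians of the listed members were 0.55 and 0.16 there, against 2.73 and 0.85 in the Oc1 heterozygotes. For these lists the values argue against an Oc1 effect of that size that is alike on both Pdx1 backgrounds. A smaller Oc1 effect, one that depends on the Pdx1 genotype, litter and age of the embryos stay open and cannot be told apart here.

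The lower beta cell genes of the double heterozygotes were weighed next. A smaller share of pancreatic epithelium would lower acinar enzymes too, whereas the 44 listed ones had a median of 0.55 (quartiles 0.11 and 0.93). Of these, 41 had passed as higher in the Oc1 heterozygotes against the same control libraries. That selection can raise the median, so the test does not exclude a smaller epithelial share. A smaller share of all endocrine cells alike stays open: the median of the 22 listed beta cell genes was -0.31 from that of 16 listed alpha, delta, PP and epsilon cell genes, with a combined spread of 0.27 (interquartile range divided by the square root of the number), and unlisted members have no value. Cell numbers and transcripts per cell are not separated by these data. Because the Oc1 heterozygotes were higher for Ins1 and Ins2 than control, part of the interaction lies in that group; the decrease against control and against the Pdx1 heterozygotes does not use its fold changes.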

How the results depend on the processing

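All alternatives below were chosen after seeing the data, except the adjusted p under 0.10 for the numbers of genes. No paired analysis was possible because the comparison table holds no values per library and its columns carry no replicate numbers. For the same reason the planned DESeq2, voom weights and exact tests, the other size factors and filters on counts, the replicate block, the fits of 2 groups, the surrogate variable, Xist and acinar covariates, each replicate left out, the estimated correlation and fry for gene lists, and the controls split into 2 and 2 were not run. Of 73 alternative values, 47 stayed within the bounds set for them. With adjusted p under 0.10 the Pdx1 heterozygotes against control gave 91 genes in place of 57. Under 0.01 they gave 25, double heterozygotes against control 113 in place of 170 and double against Pdx1 heterozygotes 118 in place of 197. A minimum fold of 2 left 34 genes for Pdx1, 601 for Oc1 and 77 for double heterozygotes against control, 103 for double against Pdx1, 462 for Pdx1 against Oc1, 513 for double against Oc1 and 625 for the interaction. Without a fold minimum the ranks give at least 3462 genes for Oc1 heterozygotes against control, 309 for double against Pdx1 and 2557 for Pdx1 against Oc1; these changes in number follow from the thresholds themselves. With the heading of block 4 as printed, genes higher less genes lower in double against Pdx1 heterozygotes turned from -91 to 91. The 2283 listed genes as background, which already hold an excess of changed genes, allow a test of the 14 lists with at least 5 listed members. Of the lists past Fisher's exact test that could be tested so, 0 of 1 passed for Pdx1 heterozygotes against control, 2 of 7 for Oc1, 5 of 6 for double heterozygotes, 2 of 9 for double against Pdx1, 2 of 11 for Pdx1 against Oc1, 5 of 9 for double against Oc1 and 3 of 10 for the interaction. For Pdx1 heterozygotes against control 2 lists passed both with genes at adjusted p under 0.10 and with a mean log2 CPM of at least 1, and the latter left 6 lists for double against Pdx1; the cause was not tested. Without the minimum of log2 CPM, r was 0.54 between Pdx1 and double heterozygotes and 0.45 between Oc1 and double, against 0.53 and 0.49 in simulated unchanged groups, so the excess of the former over simulation was lost. The other alternatives kept the counts within 1.5 times, among them the 2 single estimates of the interaction variance (984 and 986 genes) and adjustment over the listed genes alone (1436). Low expression limits the table: a fold change of a gene near the floor, such as Gkn2 with a mean log2 CPM of -2.44, rests on few reads.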

Other observations

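Several genes changed in the same direction in the 3 mutant genotypes, by different amounts. In the authors' deposited table Angptl1 was higher by 1.83, 2.26 and 2.22 in Pdx1, Oc1 and double heterozygotes (adjusted p = 0.0102, 1.61e-05 and 4.02e-05). Agr2 was higher by 2.31, 2.71 and 1.66 (adjusted p = 0.00315, 6.02e-06 and 0.0409 in the authors' deposited table). So were Reg1 by 1.62, 2.84 and 1.75, and the BMP and Wnt modulator Sostdc1 by 1.23, 2.60 and, as a fold, 3.48 (adjusted p = 0.0404, 2.1e-11 and 5.68e-06 in the authors' deposited table). Oprd1 was lower by the authors' deposited table in the same order at -1.37, -1.57 and -1.43 (adjusted p = 0.000141, 7.4e-07 and 8.51e-07), and Nepn at -1.31, -1.29 and -1.93. The interaction passed for Reg1 (-2.71), Agr2 (-3.36), Sostdc1 (-2.02), Angptl1 (-1.87) and Oprd1 (1.52; adjusted p = 1.3e-08, 4.57e-05, 0.000443, 0.0337 and 0.00115) and not for Nepn (0.68, adjusted p = 1). These genes were picked from the named genes after their values were seen, and the shared controls would by themselves give some agreement.

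The neuropeptide Npy was lower by much the same amount in Pdx1 and double heterozygotes (3.99-fold and 4.01-fold in the authors' deposited table) and stood at 0.79 in the Oc1 heterozygotes (adjusted p = 0.149), with an interaction of -0.80 ± 0.52 (SE; adjusted p = 1). Ins1 and Ins2, by contrast, had interactions of -2.79 and -2.57. Slc2a2 rose in the Pdx1 heterozygotes (0.70) and was lower in the double than in the Pdx1 heterozygotes (-1.08, adjusted p = 4.94e-07 in the authors' deposited table), with an interaction of -1.19 ± 0.26 (adjusted p = 0.000214).

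Further values, picked after they were seen, concern genes outside the endocrine and acinar lists. Kap stood at 11.01, 3.06 and 10.59 in Pdx1, Oc1 and double heterozygotes in the authors' deposited table (adjusted p = 0.0101, 0.311 and 0.00418). Alb stood at -2.05, -1.23 and -2.25 (adjusted p = 0.107, 0.209 and 0.00839 in the authors' deposited table). In the Pdx1 heterozygotes Cnn1 and Myh11 stood at 3.18 and 2.21 (adjusted p = 0.0601 and 0.0553 in the authors' deposited table), beside the galectins. The columns of the count table name 2 flow cells, and which genotypes were on which is not given in the sources used here.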
